A study of Mus musculus with 16 samples.

How the data were processed

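Gene-level RNA values were analysed for 16 libraries from the striatum of male C57BL/6J mice aged 63 days, taken 2 h after an injection of vehicle or of clozapine N-oxide (CNO) at 1 mg/kg. In each mouse RNA was taken from the cleared tissue lysate (input) and from ribosomes of astrocytes captured through a hemagglutinin tag (immunoprecipitate, IP). The libraries form 4 groups of 4, named here CNO IP, vehicle IP, CNO input and vehicle input, with replicate numbers 2 to 5 as in the sample titles. Each group was read from the injection and RNA type in the labels. The series text speaks of 4 mice, while the titles carry 8 different mouse codes, 4 per injection, each with 1 IP and 1 input library. The mouse code was taken as the animal, which gives 8 mice. If the replicates were not separate animals, the p-values measure only the spread between these samples. The labels name neither the receptor that CNO was to activate nor the virus or strain that carried the tag.

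Per the labels' protocols, IP RNA was purified with the RNeasy Micro Plus kit with removal of DNA, integrity was checked on a Bioanalyzer, and paired-end libraries were made from 100 ng of RNA with the Nugen Ovation RNA-Seq System V2 after mRNA enrichment. Per the submitters' processing notes, the tools were bcl2fastq 2.17, STAR, HTSeq and limma, with the mouse build mm10. The strand setting of the counting and the gene annotation are not given in the sources used here, so reads of overlapping genes may be shared between them, and overlaps with genes of a proper name are stated beside the genes named by fold change or named always. Of these, Rpl22, Aldh1l1, Slc1a2, Aqp4, Il6, Cmklr1, Trp53cor1, Stab2, Gli2, Fam181a, Nim1k, Txnip, Lmcd1, Gpam, Tmem98, Insc, Ctss, Saa3, Scml4, Atoh8 and Pik3ip1 overlap only gene models without a proper name, a pseudogene (Ctss) or such models and a microRNA (Gli2). Overlaps of other list members were not looked up.

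The deposited values of each library are log2 CPM as the authors made them, 17098 gene lines per library. Each value fitted log2 of a whole read number plus a prior count of 0.25 scaled to the library, divided by a normalized library size. Solving for that library size gave whole reads, within 0.01 read, for 100% of the values in every library. The recovered totals were 32.8 to 40.3 M reads (M, mega) in input and 52.1 to 61.5 M in IP. The normalized library sizes differed from these totals by factors of 0.880 to 1.14. A gene without reads stands at a log2 CPM of -7.54. The gene with the fewest reads held 29 over the 16 libraries, so genes below some count had been removed before deposit. The 10 most abundant genes took 3.23 to 3.68% of the reads in input and 6.02 to 7.13% in IP. A duplicate line with identical values was dropped, which left 17097 genes. A further 2 lines that share a date-like symbol could not be told apart and are not named.

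Each comparison was tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values (lmFit, then eBayes with a trend and robust settings), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are therefore on the scale of log2 CPM with the small prior count, and standard errors are those of limma. Genes entered a test when they had at least 15 reads in all and, in at least 4 libraries, a CPM that equals 10 reads in the median library. The comparisons were CNO with vehicle in IP, CNO with vehicle in input, IP with input in vehicle mice, IP with input in CNO mice, and the difference between the CNO effects in IP and in input, fitted as an interaction over the 16 libraries. Fits used only the groups compared. The design had named count models, a quasi-likelihood test first and a Wald test as an alternative. Neither was run, because the deposited unit is log2. Limma-voom on the recovered reads was run as an alternative.

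Gene lists for cell types and for functions, 41 in all, were fixed before the data were examined, as were the comparisons, the tests intended for counts, most alternatives and the rule for naming genes. Each list was tested with camera in limma on the deposited log2 values with a preset correlation between genes of 0.01, and again with an estimated correlation. The intended input of this test, log2 CPM with a prior count of 2, became an added alternative. Lists are described by how many measured members passed the test over all genes and how many passed when adjusted over the list alone. The list of blood cell markers had at most 1 measured member, Alas2. It is given as a gene, and counts among the 40 lists tested where it was measured. The list of mitochondrially encoded genes had 0 and was not tested. Several genes stand in more than 1 list. The immediate early and cAMP-responsive lists share Fos, Nr4a1, Nr4a2, Nr4a3, Dusp1 and Sik1, and the astrocyte markers share 7 genes with the potassium, water and gap junction list.

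Genes were named by the following rule. Thbs1, Rpl22, Chrm4, Fos, Aldh1l1, Gfap, S100b, Slc1a2, Slc1a3, Gja1, Aqp4 and Kcnj10 are always given. For CNO against vehicle, the 12 higher and 12 lower genes of largest log2 fold change in IP, and 8 and 8 in input, are named among those past the threshold with a mean of at least 1 CPM in the higher group and no overlap between the 4 CNO and 4 vehicle libraries; gene models without a proper name are counted and not named. For IP against input in vehicle mice, 8 and 8 are named by the same rule with at least 10 CPM, and the same genes are given in CNO mice. For the interaction, 6 and 6 are named without the condition on overlap. Up to 4 members of smallest p are given from each list described, and, with a few exceptions, all genes behind a list count of 5 or fewer over all genes tested.

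Gene positions came from the RefSeq annotation of GRCm38.p6, the assembly that mm10 is based on. Transcript length and GC content were those of the longest GENCODE vM21 transcript of each gene. Of the 17097 genes, 17020 matched the annotation by symbol and 16921 had a length and GC content; all 64 of the 64 genes named by fold change or named always had a position. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for recovery of reads, lookups and plots.

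The tests were checked on simulated reads drawn from the real means and library sizes with 200 changed genes. Recovery is given over those that passed the filter. Within a comparison every gene had the same dispersion between libraries, the median over well-counted genes (0.00467 to 0.00611 over the comparisons). The shares below therefore do not cover genes of wider spread. For CNO against vehicle in IP, with 15532 genes, 86.6% of genes changed 1.5-fold, 97.0% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 3.59% of calls were false. For input, with 15771 genes, the shares were 78.8, 97.0 and 100% with 4.69% false calls. For IP against input they were 88.1, 100 and 100% in vehicle (15826 genes, 3.54% false) and 91.0, 95.5 and 100% in CNO (15722 genes, 4.04% false). For the interaction, with 16077 genes, they were 80.6, 83.6 and 98.4% with 4.95% false calls. In the simulation for CNO against vehicle in IP, camera called the changed list of 20 genes and 0 of 50 unchanged lists, as did fry. The simulated genes varied independently, so how these tests treat lists whose members move together was not checked.

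Within a group the libraries correlated at 0.967 to 0.988 over genes, and no pair was as close as sampling noise (lowest chi-square per degree of freedom 8.23). That does not tell separate animals from separate preparations of 1 animal, and the mouse codes alone are the ground for counting each library as 1 replicate. IP and input of 1 mouse share an animal by their titles, and the values bear a trace of it: over 12117 genes, the deviations from the group means correlated between IP and input of the same mouse at 0.407 to 0.697 in CNO and 0.302 to 0.682 in vehicle mice, and 8 of 8 pairs were closest with their own partner. The fit without the mouse as a block was the planned one, and the blocked result is given where it changes a call or count.

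The alternatives were size factors by median of ratios, upper quartile scaling, no filter, a filter of 1 CPM in 4 libraries, limma-voom, a minimum 2-fold change, pseudocounts of 0.1 and 5, a replicate block, 1 fit of all 16 libraries, camera with an estimated correlation, fry, and leaving out each library in turn (each mouse in turn for the interaction). The pseudocount of 1 and the prior count of 2 for the lists were added after the data were seen. No group that received CNO without the receptor is analysed here.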

Results

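RNA abundance was measured in the striatum of mice 2 h after CNO or vehicle, in astrocyte ribosome IP and in whole-lysate input. CNO is a synthetic ligand used to activate designer receptors, and the series title gives activation of Gi signalling in striatal astrocytes as the subject. The 16 libraries comprise 4 CNO IP, 4 vehicle IP, 4 CNO input and 4 vehicle input libraries, with 52.1 to 61.5 M reads assigned to genes per IP library and 32.8 to 40.3 M per input library. Values are the authors' log2 CPM, n = 4 libraries per group throughout, and every adjusted p of a gene is from limma and of a list from camera.

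The first comparison asks which transcripts the ribosome capture took up in vehicle mice. Astrocyte transcripts were higher in IP than in input: 36 of 36 astrocyte markers passed (36 adjusted over the list alone), with a median log2 ratio of 2.65. Among genes of at least 10 CPM that met the rule for naming, the largest ratios were those of Atp1b2, a subunit of the sodium pump of astrocytes (log2 ratio 3.86, SE 0.06), the glutamate transporter Slc1a2 (3.79, SE 0.16), the potassium channel Kcnj10 (3.65, SE 0.07) and the transcription factor Sox9 (3.50, SE 0.09). The hedgehog transcription factor Gli2 (3.49, SE 0.20), the thrombospondin Thbs4 (3.48, SE 0.27), the Hippo pathway transcription factor Tead1 (3.45, SE 0.07) and the nuclear receptor Rorb (3.34, SE 0.10) followed. Aldh1l1 (2.92), Gfap (3.13), S100b (1.76), the glutamate transporter Slc1a3 (2.78), the gap junction gene Gja1 (2.99) and the water channel gene Aqp4 (2.88) were also higher in IP. Transcripts of microglia, medium spiny neurons and endothelium were lower in IP: 20 of 20 microglia markers (median log2 ratio -4.37; 20 adjusted over the list alone), 21 of 21 medium spiny neuron markers (-1.55; 21 alone) and 17 of 18 endothelial markers (-2.33; 17 alone).

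Among genes of at least 10 CPM that met the naming rule, the lowest ratios were those of Rmrp, the RNA of the RNase MRP complex (log2 ratio -6.38, SE 0.14), the myeloid genes Ly6c2 (-6.09, SE 0.96), Lyz2 (-5.93, SE 0.89), Ctss (-5.79, SE 0.47), C1qa (-5.42, SE 0.51) and Tyrobp (-5.39, SE 0.37), the acute phase gene Saa3 (-5.72, SE 1.23) and Igj, which encodes the joining chain of antibodies (-5.70, SE 0.79). The ratio of Saa3 was not past the threshold with limma-voom. Of the neuronal genes, Tac1 (-2.43), Arpp21 (-2.33), the dopamine receptor Drd1a (-1.66) and the adenosine receptor Adora2a (-2.06) are examples of the lower medium spiny neuron markers. Cytosolic ribosomal protein transcripts were lower for 76 of 80 members and higher for Rps4l (0.31; 76 lower and 1 higher adjusted over the list alone), with a median log2 ratio of -1.64. Rps4l was not past the threshold with upper quartile scaling. Rpl22, the gene a ribosome tag is usually placed on, was higher in IP (log2 ratio 1.08), as was the muscarinic receptor gene Chrm4 (4.49-fold), whose annotation overlaps Mdk (log2 ratio 2.32). Thbs1 did not differ (-0.30, SE 0.28, adjusted p = 0.345).

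Interneuron and ependymal transcripts stood with the astrocyte markers on the higher side. Of 12 striatal interneuron markers 9 were higher (9 higher and 1 lower adjusted over the list alone; median log2 ratio 1.86), among them Nos1 (3.24), Npy (1.99), Lhx6 (1.78) and Sst (1.93). Of 12 ependymal markers 11 were higher (11 adjusted over the list alone; median 1.99), among them Foxj1 (2.62) and Tekt1 (2.75). Oligodendrocyte markers were higher for 12 of 18 members (10 adjusted over the list alone; median 0.70). As a list they missed the threshold (adjusted p = 0.0548). Pericyte markers were higher for 2 of 13, Notch3 (3.06) and Pdgfrb (1.49), and lower for 7 (the same alone; adjusted p = 0.0917). Fibroblast and meningeal markers were lower for 8 of 10 (8 adjusted over the list alone; median -2.69; adjusted p = 0.0126, and adjusted p = 0.468 with an estimated correlation). Pan-neuronal markers were higher for 4, among them Tubb3 (0.46), Syn1 (0.39) and Map2 (0.24), and lower for 9 of 20 (the same alone; adjusted p = 0.172). Syn1 and Map2 lost their calls with upper quartile scaling (adjusted p up to 0.289). Excitatory postsynaptic genes were higher for 3, among them Homer3 (2.07) and Dlgap1 (0.42), and lower for 13 of 20 (the same alone). Dlgap1 lost its call with upper quartile scaling (0.158) and without vehicle input replicates 2, 3 or 5 or vehicle IP replicates 2, 3 or 4 (up to 0.0815). The list's call (adjusted p = 0.0396) was lost with an estimated correlation (0.796), with the mouse as a block (0.0736), without vehicle IP replicate 2 (0.0547) and without vehicle IP replicate 5 (0.0587).

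In all, 5978 genes were higher and 5924 lower in IP among 15903 tested, 2443 and 2308 of them at least 2-fold. Camera called 13 lists higher and 6 lower, with adjusted p = 6.69e-15 for astrocyte markers, 3.09e-08 for medium spiny neuron markers, 7.01e-08 for microglia, 1.54e-07 for endothelial markers, 1.84e-19 for ribosomal proteins, 0.00285 for interneuron and 0.00301 for ependymal markers. None of these list calls held with an estimated correlation (adjusted p = 0.220, 0.468, 0.468, 0.220, 0.220, 0.427 and 0.638 in that order). The statements above therefore rest on counts of members, to be read beside the 5978 higher and 5924 lower of all 15903 genes. Members of 1 list may move together, so such a count is not a test of the list. Upper quartile scaling shifted the median of all genes by -0.15 on the log2 scale in this comparison, and the share of calls that were higher was 40.7% with it and 50.2% as deposited. In CNO mice 6315 genes were higher and 5546 lower in IP among 15801 tested, 2592 and 2090 at least 2-fold. There, upper quartile scaling shifted the median by -0.21 and gave 40.2% of calls higher against 53.2%. Of the 15654 genes tested in both, 5406 were higher and 4966 lower in both (2386 and 2045 for independent lists). Slc1a2 had a log2 ratio of 3.66 in CNO mice, Kcnj10 3.28, Atp1b2 3.45, Sox9 3.35, Gli2 2.70, Thbs4 3.24, Tead1 3.27, Rorb 3.42, Rmrp -6.83, Ly6c2 -5.72, Lyz2 -6.04, Ctss -5.96, Saa3 -6.66, Igj -5.78, C1qa -5.43 and Tyrobp -5.55.

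**Figure D1:**
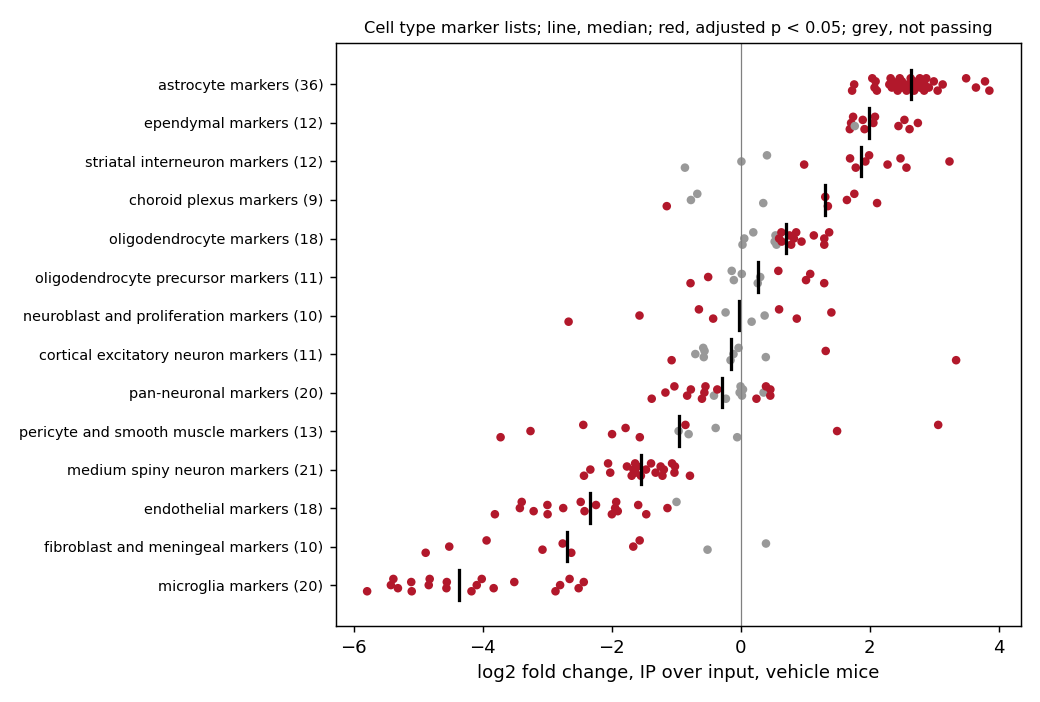
Log2 ratio of IP to input in vehicle mice (n = 4 and 4 libraries) for the measured members of the cell type lists, each point 1 gene. All 36 astrocyte markers lie above 0 and all 20 microglia markers below, with medians of 2.65 and -4.37; upper quartile scaling shifted the median of all genes by -0.15.

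The second comparison asks what CNO changed in the RNA of the astrocyte ribosome IP. Interneuron and ependymal markers were also higher in IP than in input, so a change in IP is not assigned to astrocytes alone. No group that received CNO without the receptor is analysed, so effects of CNO apart from the receptor are not separated. Thbs1, which encodes the secreted matrix protein thrombospondin 1, rose 38-fold, from 1.65 to 62.1 CPM (log2 fold change 5.25, SE 0.20, adjusted p = 3.13e-07), and the immediate early gene Fos rose 10.9-fold, from 28.2 to 301 CPM (log2 3.45, SE 0.23, adjusted p = 1.55e-05). Thbs1 lies on chromosome 2 at 118111876 to 118127133 and Fos on chromosome 12 at 85473890 to 85477274 of GRCm38, both protein coding. Tinf2, a component of the telomere-protecting shelterin complex, went from 11.7 to 521 CPM (log2 5.48, SE 0.10, adjusted p = 6.67e-09), and its annotation on chromosome 14 (55676208 to 55682159) overlaps Gmpr2.

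The interleukin family cytokine Il11 (chromosome 7, 4772373 to 4782907, overlapping Tmem190) rose from 0.381 to 72.5 CPM (log2 7.63, SE 0.22, adjusted p = 9.88e-08). Maff, a small Maf transcription factor, rose by log2 6.01 (SE 0.25) from 3.6 to 220 CPM. Sphk1, which phosphorylates sphingosine, rose by 6.43 (SE 0.27), the chemerin receptor Cmklr1 by 5.85 (SE 0.15, adjusted p = 3.20e-08), the cytokine Il6 by 6.77 (SE 0.89, adjusted p = 0.00102), the actin-binding Cnn1 by 5.51 (SE 0.48) and the stress transcription factor Atf3 by 5.34 (SE 0.28). Some of the largest fitted increases were at low counts. The orphan receptor gene Gprc5a had 960 reads in CNO and 5 in vehicle IP, a pooled CPM ratio of 203 (95% exact interval 86.8 to 627). The urocortins Ucn and Ucn2, peptides of the corticotropin-releasing factor family, had ratios of 248 (44.0 to 9823, from 1 vehicle read) and 77.0 (29.8 to 284), and Trim38 45.9 (20.8 to 126); these intervals cover counting error only. Each of the genes above was higher in 4 of 4 CNO libraries than in every vehicle library. The naming rule required this of all of them but Thbs1 and Fos.

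Of the genes that fell and met the naming rule, Hes5, a target of Notch signalling, had the largest change (log2 -1.92, SE 0.39, adjusted p = 0.0104, 4.58 against 16.5 CPM). Trp53cor1, a long non-coding RNA, fell by 1.68 (SE 0.14), Smad6, an inhibitor of bone morphogenetic protein signalling, by 1.62 (SE 0.22), the ectodysplasin receptor Edar by 1.60 (SE 0.24) and the scavenger receptor Stab2 by 1.56 (SE 0.30), all on the log2 scale. Gli2 fell by 1.5 (SE 0.23), the Wnt receptor Fzd10 by 1.49 (SE 0.26), Fam181a by 1.47 (SE 0.21), Nim1k by 1.32 (SE 0.08), the receptor gene Pdgfrb by 1.31 (SE 0.16, adjusted p = 7.13e-04), Shisa2 by 1.31 (SE 0.21) and Txnip, a thioredoxin-interacting protein, by 1.29 (SE 0.25). Astrocyte genes that are always given moved little. Gja1 fell by 0.30 (SE 0.08, adjusted p = 0.0247), a call lost without CNO IP replicates 2, 4 or 5 or vehicle IP replicates 2, 3 or 4 (adjusted p up to 0.0776). S100b fell by 0.22 (SE 0.06, adjusted p = 0.0461), a call lost without any of CNO IP replicates 2 to 5 or vehicle IP replicates 2 to 4 (up to 0.118). Values that did not pass were 0.32 for Gfap (SE 0.26), -0.02 for Aldh1l1, -0.05 for Slc1a2, 0.03 for Slc1a3, -0.17 for Aqp4, -0.13 for Kcnj10, 0.06 for Rpl22 and 0.17 for Chrm4.

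In total, 1598 genes rose and 1102 fell among 15598 tested, and 380 of the increases and 49 of the decreases were at least 2-fold. With upper quartile scaling the number of decreases was 1946, and 39.3% of calls were higher against 59.2% as deposited, so the balance between small increases and small decreases rests on the scaling. The number of decreases was 717 with the replicate number as a block, 726 without CNO IP replicate 4, 596 without vehicle IP replicate 2 and 716 without vehicle IP replicate 4.

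**Figure D2:**
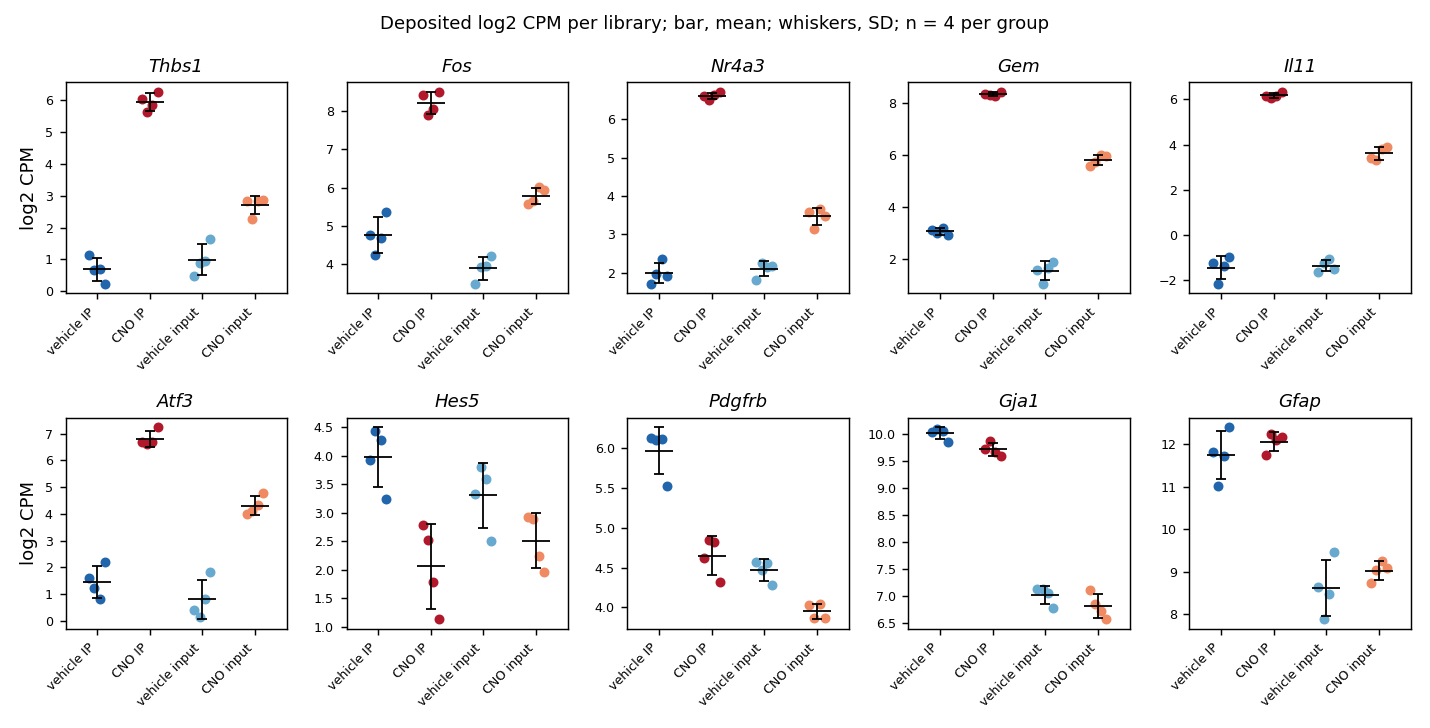
Log2 CPM of 10 genes in each library (points) of the 4 groups, with the group mean (bar) and SD (whiskers), n = 4 per group; the genes were chosen for the plot after their values were seen. Thbs1 averaged 62.1 CPM in CNO IP and 1.65 CPM in vehicle IP, and Hes5 averaged 4.58 and 16.5 CPM.

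Immediate early genes rose together in IP. Of 31 members 25 rose and 1 fell (25 and 1 adjusted over the list alone), with a median log2 change of 1.77. Nr4a3 rose by 4.63 (SE 0.12), Fosl2 by 3.57 (SE 0.13), Fosb by 2.87 (SE 0.09) and Gadd45g by 2.44 (SE 0.09). Klf2, a transcription factor of endothelium, fell by 0.69, a call lost without CNO IP replicates 2, 4 or 5 or vehicle IP replicates 2, 3 or 4 (adjusted p up to 0.108). The activity-regulated neuronal genes Arc, Npas4 and Egr4 were among the 5 that did not pass, with Egr3 and Ier5. Of 15 cAMP-responsive genes 14 rose and Ppargc1a fell by 0.32 (14 and 1 adjusted over the list alone; median 1.57). Gem rose by 5.26 (SE 0.07), Crem by 2.30 and Dio2 by 1.67. This list shares 6 members with the immediate early list. Of 16 SRF and YAP target genes 10 rose (10 higher and 1 lower adjusted over the list alone; median 0.55), among them the actin crosslinker Flna (2.46), Cyr61 (3.29) and Thbs1. Of 18 MAP kinase feedback genes 11 rose and Spred1 (-0.22) and Etv4 (-0.32) fell (13 and 2 adjusted over the list alone), with Dusp5 at 3.0, Myc at 2.72, Ier3 at 2.65 and Spry4 at 1.27. The call of Etv4 was lost without CNO IP replicates 3 or 4 or vehicle IP replicate 2 (adjusted p up to 0.0535). The adjusted p of camera was 1.20e-22 for immediate early genes, 1.11e-15 for cAMP-responsive genes and 2.06e-07 for SRF and YAP targets. These 3 lists held with an estimated correlation (adjusted p = 0.0349 for each). The MAP kinase feedback list (adjusted p = 1.12e-06) had adjusted p = 0.236 with an estimated correlation.

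Genes of cholesterol synthesis and of protein folding in the endoplasmic reticulum also rose in CNO IP. Of 25 cholesterol synthesis genes 20 rose and none fell (20 adjusted over the list alone; median log2 0.97), including the mevalonate pathway kinases Pmvk (3.39, SE 0.08) and Mvk (2.51), and Hsd17b7 (2.07). Srebf2, Ebp and Tm7sf2 were among the members that did not pass. Of 24 unfolded protein response genes 20 rose (20 adjusted over the list alone; median 0.43), including the chaperone Hspa5 (1.27), Atf4 (1.57) and Xbp1 (1.06). The members Pdia4, Edem1, Asns and Canx did not pass. Cytosolic ribosomal protein transcripts rose for 20 of 79 (30 adjusted over the list alone) with a small median of 0.21. Rps4x rose by 0.46, Rpl32 by 0.36, Rpl21 by 0.32 and Rplp0 by 0.31. The adjusted p values of camera were 1.28e-18, 9.15e-15 and 2.05e-10. None of the 3 lists held with an estimated correlation (adjusted p = 0.25 for cholesterol synthesis, adjusted p = 0.210 for the unfolded protein response and adjusted p = 0.359 for ribosomal proteins).

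Of 12 A2 genes, defined as induced by ischaemia, 10 rose (10 adjusted over the list alone; median log2 1.63), with Sphk1, the cytokine Clcf1 (3.78), the pentraxin Ptx3 (3.33) and B3gnt5 (1.68). Of 13 pan-reactive genes 4 rose (5 adjusted over the list alone), S1pr3 by 2.05, Cd44 by 1.63, Osmr by 1.5 and the small heat shock protein Hspb1 by 1.24. The call of Osmr was lost without CNO IP replicate 4 or 5 (adjusted p up to 0.0553). Of 12 A1 genes, defined as induced by endotoxin, Fkbp5 rose by 1.00 and Amigo2 fell by 0.29 (1 and 1 adjusted over the list alone). Amigo2 lost its call without 6 of the 8 libraries, those of CNO replicates 2, 4 and 5 and vehicle replicates 2, 3 and 4 (up to 0.114). Camera gave adjusted p = 4.01e-07 for A2, adjusted p = 0.0170 for pan-reactive and adjusted p = 0.982 for A1 genes, where the test pointed down while the median (0.06) and mean (0.04) were above 0. With an estimated correlation A2 and pan-reactive genes had adjusted p = 0.319 and adjusted p = 0.903. The pan-reactive call was also lost without vehicle IP replicate 3 (0.0780). A test of the difference between these lists was not made.

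In most cell type lists few or 0 markers passed in CNO IP. Of the astrocyte markers 10 of 36 passed, beside 2700 of all 15598 genes tested. Of 36 astrocyte markers 3 rose, Ppp1r3c (1.62), F3 (0.67) and Htra1 (0.47), and 7 fell, Bmpr1b (-0.83), Cldn10 (-0.59), Fam107a (-0.49), Gldc (-0.38), Gpr37l1, Gja1 and S100b (3 and 9 adjusted over the list alone; median log2 -0.17). Of 18 endothelial markers Ptprb fell by 0.34 (1 adjusted over the list alone; median -0.17), a call lost without CNO IP replicate 4 or 5 or vehicle IP replicate 2 (adjusted p up to 0.0653). Both lists were called lower, astrocyte markers with adjusted p = 0.0203 and endothelial markers with adjusted p = 0.0212. Neither held with an estimated correlation (adjusted p = 0.903 and adjusted p = 0.639). Astrocyte markers lost their call without CNO IP replicate 5 (0.0817) or vehicle IP replicate 3 (0.0592). Endothelial markers lost it without CNO IP replicate 5 (0.0516) or vehicle IP replicate 5 (0.103). Of 21 medium spiny neuron, 12 interneuron and 18 oligodendrocyte markers 0 passed in limma, 0 had an unadjusted p under 0.05 and limma-voom called 0. Ependymal, fibroblast, oligodendrocyte precursor, neuroblast and choroid plexus markers also had 0 calls in limma and in limma-voom, with 3, 1, 1, 3 and 0 at an unadjusted p under 0.05. Single members passed in other lists: Rorb of the cortical list (1.24), Cd68 of the microglia list (1.17) and Homer1 of the excitatory postsynaptic genes (0.56). In the pericyte list Tagln (1.33) and Pdgfrb (-1.31) passed. Rorb and Pdgfrb were themselves higher in IP than in input in vehicle mice, so their changes are not assigned to cortical neurons or pericytes. Snhg11 (0.28) and Meg3 (0.31) rose among 20 pan-neuronal markers, and Meg3 lost its call without CNO IP replicate 2 or vehicle IP replicates 2 or 4 (up to 0.0589). Adjusted over the list alone these counts were the same. Of these lists, the cortical markers had a median of -0.31 and a mean of -0.13 while the test pointed up, and the microglia markers a median of -0.05 and a mean of 0.04 with the test up. The neuroblast markers had a median of -0.03 and a mean of -0.07 with the test up (adjusted p = 0.998 for each of the 3).

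Over the list tests of this comparison, 12 lists were called higher and 2 lower among 39, and 3 held with an estimated correlation. The number of lower lists was 5 without CNO IP replicate 3, 4 without CNO IP replicate 4 and 0 without CNO IP replicate 5.

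**Figure D3:**
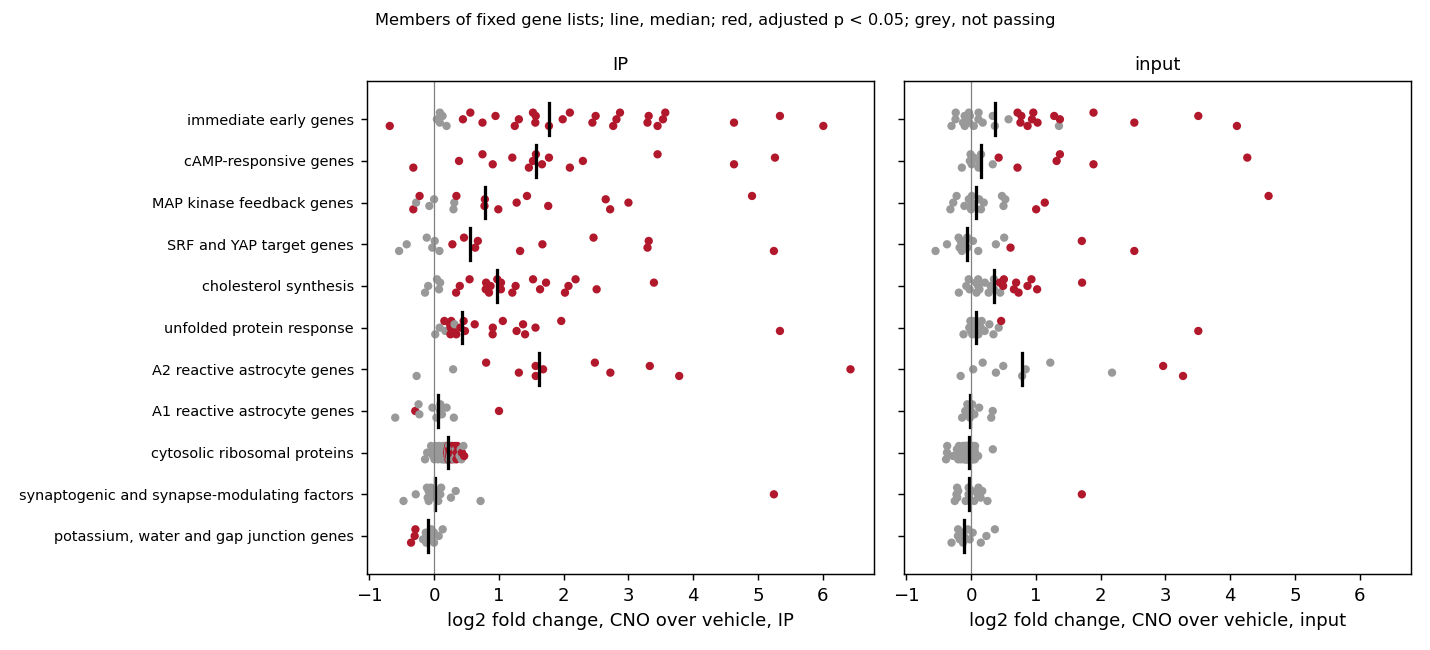
Log2 fold change of CNO over vehicle for the measured members of 11 lists, in IP and in input, each point 1 gene (n = 4 and 4 libraries in each RNA type). The medians of immediate early genes were 1.77 in IP and 0.37 in input, and those of cholesterol synthesis genes 0.97 and 0.35.

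The third comparison asks what CNO changed in RNA of the whole striatal lysate. Fewer genes passed and most of them rose. Il11 rose by 4.98 on the log2 scale (SE 0.20, adjusted p = 7.73e-07), the transcription factor Fosl1 (overlapping Ccdc85b) by 4.59 (SE 0.48), the small GTPase Gem by 4.26 (SE 0.17, adjusted p = 1.76e-06), Maff by 4.10 (SE 0.19). Atf3 rose by 3.51 (SE 0.35), Socs3, an inhibitor of cytokine signalling, by 3.39 (SE 0.40, adjusted p = 0.00927), Sphk1 by 3.27 (SE 0.43) and Il6 by 3.13 (SE 0.33). Thbs1 rose by 1.71 (SE 0.24, adjusted p = 0.00674), from 2.07 to 6.58 CPM. Fos rose by 1.89 (SE 0.15, adjusted p = 3.68e-04), from 15.1 to 55.6 CPM. Of the genes that fell, the lipid synthesis gene Gpam (-0.75, SE 0.08, adjusted p = 9.00e-04) and Lmcd1 (-0.87, SE 0.12) kept their call without any 1 library. Lmcd1 lost its call with the replicate number as a block. The other lowest genes were the endothelial Clec14a (-0.94, SE 0.18) and tight junction gene Cldn5 (-0.63, SE 0.12), the Notch target Nrarp (-0.79, SE 0.13), Nat1 (-0.74, SE 0.15), Tmem98 (-0.67, SE 0.12) and Insc (-0.65, SE 0.10).

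These other decreases were close to the threshold. Without 1 library the adjusted p reached 0.130 for Clec14a (lost without each library but vehicle input replicate 5), 0.131 for Cldn5 (lost without CNO input replicates 2, 3 or 5 or vehicle input replicates 2, 4 or 5), 0.105 for Nrarp (CNO replicates 3 to 5, vehicle replicates 2 to 4), 0.164 for Nat1 (each of the 8), 0.109 for Tmem98 (CNO replicates 2 and 3, vehicle replicates 2 to 5) and 0.0552 for Insc (vehicle input replicate 2). Of the genes always given, only Thbs1 and Fos passed. Gfap had a log2 change of 0.41, Kcnj10 0.24, Gja1 -0.20, Aqp4 -0.20, Aldh1l1 -0.12, S100b -0.12, Slc1a2 0.08, Slc1a3 -0.01, Rpl22 0.02 and Chrm4 0.02.

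Immediate early genes rose for 13 of 31 members in input (16 adjusted over the list alone), with Cyr61 at log2 2.52 and Gadd45g at 1.28. Of 15 cAMP-responsive genes 6 rose (7 adjusted over the list alone), with Nr4a3 at 1.37 and Dio2 at 1.32. Of 25 cholesterol synthesis genes 10 rose (14 adjusted over the list alone), with Pmvk at 1.71, Mvk at 1.02, Mvd at 0.93 and Msmo1 at 0.87. Of 18 MAP kinase feedback genes Fosl1, Ier3 (1.14) and Myc (1.00) rose (6 adjusted over the list alone). Of 11 A2 genes Ptx3 (2.97) and Sphk1 rose (7 alone), and of 24 unfolded protein response genes Atf3 and Atf4 (0.46; 2 alone). The adjusted p of camera was 3.36e-17, 1.77e-10, 4.83e-20, 1.16e-04, 2.63e-08 and 5.19e-05 for these 6 lists. None held with an estimated correlation (adjusted p = 0.199, 0.191, 0.191, 0.236, 0.204 and 0.563). SRF and YAP target genes were not called as a list (adjusted p = 0.108), with Cyr61, Thbs1 and Flna (0.61) higher (3 alone), a median of -0.06, and a mean of 0.25 and a test that pointed up.

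Of 18 endothelial markers Slco1a4 (-0.53) and Cldn5 fell (9 adjusted over the list alone; median log2 -0.29; adjusted p = 2.85e-09), and of 13 pericyte markers Pdgfrb (-0.52; 1 alone; adjusted p = 0.00671). With an estimated correlation these lists had adjusted p = 0.197 and adjusted p = 0.236. Slco1a4 lost its call without CNO input replicates 2, 3 or 5 or vehicle input replicates 2, 3 or 4 (adjusted p up to 0.117). Cldn5 lost its call without CNO input replicates 2, 3 or 5 or vehicle input replicates 2, 4 or 5 (up to 0.131), and Pdgfrb lost it without CNO input replicates 3 or 5 or vehicle input replicates 2, 3 or 4 (up to 0.0842). Pdgfrb was higher in IP than in input in vehicle mice, so its fall is not assigned to pericytes. Fibroblast and meningeal markers (10 members, adjusted p = 0.0200) and oligodendrocyte markers (18 members, adjusted p = 0.00441) were called lower as lists with 0 members past limma or limma-voom and 4 each at an unadjusted p under 0.05 (0 adjusted over the list alone). They had adjusted p = 0.563 and adjusted p = 0.705 with an estimated correlation. The fibroblast and meningeal markers lost that call without CNO input replicate 4 (0.0520) or vehicle input replicate 4 (0.133). The oligodendrocyte markers lost it without CNO input replicate 5 (0.108) or vehicle input replicate 3 (0.0638). Pan-reactive genes, choroid plexus markers and excitatory postsynaptic genes were called higher with 0 members past limma or limma-voom and 5 (4 higher and 1 lower), 1 and 1 at an unadjusted p under 0.05 (2, 1 and 0 adjusted over the list alone; adjusted p = 0.00150, 0.0108 and 0.0460; adjusted p = 0.563, 0.197 and 0.411 with an estimated correlation). Choroid plexus markers lost the call without vehicle input replicate 5 (0.0651). Excitatory postsynaptic genes lost it without CNO input replicates 4 (0.0502) or 5 (0.236) or vehicle input replicates 4 (0.108) or 5 (0.126). Of astrocyte markers Ppp1r3c (1.24) and F3 (0.55) rose and Gldc (-0.43) fell (3 and 5 adjusted over the list alone; adjusted p = 0.113), Gldc with up to adjusted p = 0.106 without CNO input replicates 3 or 4 or vehicle input replicates 2, 3 or 4. Gpr34 fell by 0.36 among microglia markers (3 alone; adjusted p = 0.360), with up to adjusted p = 0.144 without each library but vehicle input replicate 3.

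In input 129 genes rose and 29 fell among 15825 tested. Of the increases 59 were at least 2-fold, and of the decreases 0, in limma. In 1 fit of all 16 libraries 196 rose and 105 fell. The number that rose was 85 without CNO input replicate 5. The number that fell was 7 with the replicate number as a block, 8 without CNO input replicate 3, 8 without CNO input replicate 5, and 4, 11 and 8 without vehicle input replicates 2, 3 and 4. Camera called 13 lists higher and 4 lower among 40, and 8 lower without CNO input replicate 2. With an estimated correlation 0 lists were called. Of the 15267 genes tested in both RNA types, the 129 that rose in input all rose in IP (1576 there; 13.3 for independent lists), and 16 of the 29 that fell in input fell in IP (1095 there; 2.08 for independent lists). The same mice gave both, so the excess is not a count from independent animals.

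The last comparison asks whether the CNO effect differed between IP and input. It was larger in IP for many of the genes that rose. The difference is signed, the log2 change in IP minus that in input. Below, a larger effect is a difference above 0 and a smaller effect one below 0. A gene that fell further in IP than in input therefore counts as smaller. The difference on the log2 scale was 3.54 for Thbs1 (SE 0.33, adjusted p = 4.25e-06) and 1.56 for Fos (SE 0.30, adjusted p = 0.00516). It was 5.18 for Cmklr1 (SE 0.28, adjusted p = 8.63e-09), which had 38.5 and 0.678 CPM in CNO and vehicle IP and 8.53 and 5.62 CPM in input. It was 3.26 for the nuclear receptor Nr4a3 (SE 0.19, adjusted p = 2.26e-08) and 3.16 for Sphk1 (SE 0.54). It was 5.4 for Ucn (SE 1.46, adjusted p = 0.0441) and 3.63 for Il6 (SE 0.99, adjusted p = 0.0479). On the lower side were Nim1k (-0.88, SE 0.10), Pik3ip1 (-0.88, SE 0.10), Trp53cor1 (-1.08, SE 0.23), Scml4 (-1.31, SE 0.31), Shisa2 (-1.21, SE 0.31) and Atoh8 (-1.13, SE 0.27). Nim1k, Trp53cor1 and Shisa2 fell in CNO IP by more than these differences, so they fell further in IP than in input.

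Without 1 mouse the call was lost for Ucn (each CNO mouse, vehicle mice 2 or 3; adjusted p up to 0.158), Il6 (each CNO mouse, vehicle mice 3 or 5; up to 0.148), Shisa2 (CNO mice 3 or 5, vehicle mice 2, 3 or 4; up to 0.137), Atoh8 (CNO mice 4 or 5, vehicle mice 3 or 4; up to 0.10) and Scml4 (CNO mice 2 or 3, vehicle mice 2 or 3; up to 0.0775). Ucn was also lost with upper quartile scaling (0.0547), and Il6 with upper quartile scaling (0.0525), median-of-ratios size factors (0.0542) and limma-voom (0.0636).

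Camera called 9 lists with a log2 change higher in IP than in input and 0 with one lower in IP. Of the members, 22 of 31 immediate early genes had a larger effect in IP (25 adjusted over the list alone; median difference 1.19), among them Fosl2 (2.79), Klf4 (2.51) and Fosb (2.11). So did 11 of 15 cAMP-responsive genes (13 larger and 1 smaller alone; Crem 1.58, Sik1 1.19, Pde4b 1.15) and 9 of 16 SRF and YAP target genes (9 alone; Flna 1.85, Zyx 1.56). These 3 lists (adjusted p = 1.21e-25, 1.57e-16 and 2.82e-11) held with an estimated correlation (adjusted p = 0.0249, 0.00419 and 0.00419). Of the cholesterol synthesis genes 18 had a larger effect (19 alone; Pmvk 1.68, Mvk 1.49), of the MAP kinase feedback genes 8 (10 larger and 1 smaller alone; Dusp5 2.50) and of the unfolded protein response genes 10 (13 alone; Atf4 1.10). They had adjusted p = 2.69e-21, 2.02e-07 and 2.82e-11, and 0.0723, 0.0921 and 0.344 with an estimated correlation. Camera also called ribosomal proteins, where Rps4x passed (0.57; 1 alone), A2 genes, where Sphk1 and Clcf1 (2.56; 4 alone) passed, and glycolysis genes, where Slc2a1 (0.73), Pfkfb3 (0.98), Slc16a3 (0.67) and Hk2 (1.49; 5 alone) passed. They had adjusted p = 1.56e-10, 0.0217 and 0.00375, and 0.736, 0.974 and 0.355 with an estimated correlation. The A2 genes lost that call without CNO mouse 4 (0.0569), vehicle mouse 4 (0.0521) or vehicle mouse 5 (0.0550). Slc16a3 lost its call without each mouse but vehicle 3 (up to 0.156) and Hk2 without each CNO mouse or vehicle mice 2 or 4 (up to 0.162), and both lost it with either other scaling.

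The log2 change was higher in IP than in input for 680 genes and lower for 93 among 16287 tested (170 and 4 by at least 2-fold). With the mouse as a block the numbers were 1018 and 222. The share of calls that were higher in IP was 88.0%, 73.3% with upper quartile scaling and 78.3% with median-of-ratios size factors. The number lower in IP was 198 and 155 with these scalings and 154 with a pseudocount of 5. It was 49, 50 and 57 without CNO mice 3, 4 and 5, and 35 and 40 without vehicle mice 2 and 4.

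**Figure D4:**
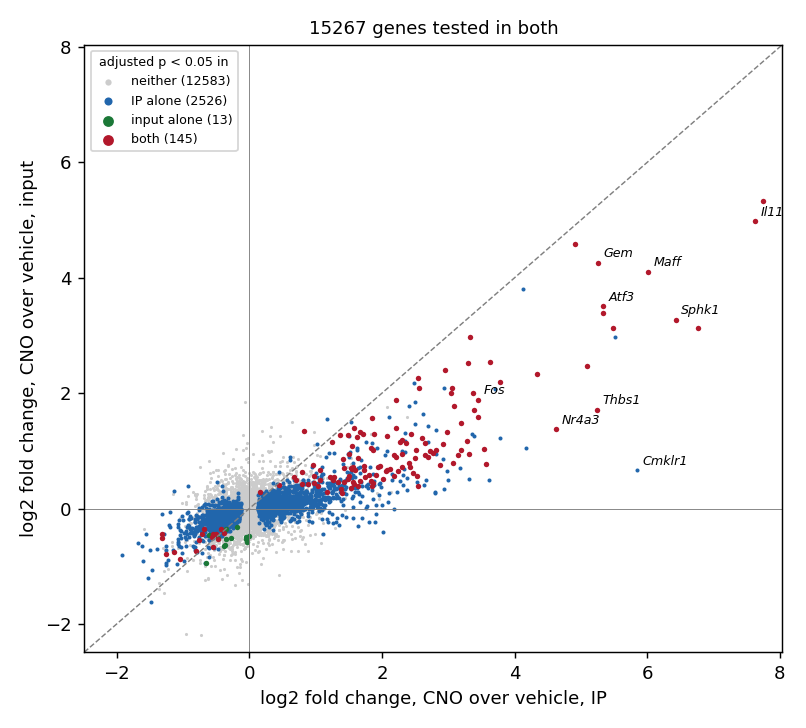
Log2 fold change of CNO over vehicle in IP (horizontal) against that in input (vertical) for the 15267 genes tested in both, n = 4 and 4 libraries in each RNA type, with a dashed line where both effects are equal. Of these genes 145 were called in both, 2526 in IP alone, 13 in input alone and 12583 in neither.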

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

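The test of the dilution explanation below was planned before its value was seen, but the reading of its interval was made stricter afterwards. For the depth test, counting only the genes that passed again was chosen after the counts were seen; no other test in this part was chosen after the result was seen. Single libraries were compared with the other 3 of their group by the Dixon criterion in 247 groups of 4 values, and 19 stood apart; chance alone marks about 1 in 20 such groups.

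In CNO IP, replicate 5 had an S100b value of 8.24 log2 CPM against 8.36 to 8.37 in the others and an Atf3 value of 7.24 against 6.62 to 6.68, and replicate 3 had a Fosl1 value of 4.49 against 4.60 to 4.61. In vehicle IP, replicate 4 held the only Ucn read (-5.37 log2 CPM, the others at -7.54), replicate 3 had a Fam181a value of 2.88 against 3.18 to 3.20, and replicate 2 had 58.3 M reads against 59.0 M in the others. Vehicle IP replicate 5 had a Pdgfrb value of 5.52 against 6.10 to 6.12, a Fosl1 value of 0.84 against -0.81 to -0.56, and a mean over the astrocyte markers of 8.82 log2 CPM against 9.01 to 9.03.

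In CNO input, replicate 3 had a Thbs1 value of 2.27 log2 CPM against 2.82 to 2.86 and a Cnn1 value of -0.77 against 0.26 to 0.42, replicate 4 had a mean over the neuroblast and proliferation markers of 1.84 against 2.05 to 2.07, and replicate 5 had 40.1 M reads against 32.8 M in the others. CNO input replicate 2 had a Kcnj10 value of 6.76 against 5.44 to 5.62, a Tinf2 value of 6.40 against 6.62 to 6.65, a mean over the interneuron markers of 4.22 against 3.69 to 3.74, and a mean over the oligodendrocyte precursor markers of 4.89 against 4.70 to 4.73. In vehicle input, replicate 5 had an Slc1a2 value of 10.10 log2 CPM against 10.56 to 10.64 and a Clec14a value of 2.49 against 1.85 to 1.92.

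By the interaction test the log2 change with CNO was higher in IP than in input for 680 genes and lower for 93. The lower side takes in genes that fell further in IP. The log2 differences of the named genes were 5.4 for Ucn, 5.18 for Cmklr1, 3.63 for Il6, 3.54 for Thbs1, 3.26 for Nr4a3, 3.16 for Sphk1 and 1.56 for Fos, and -1.31 for Scml4, -1.21 for Shisa2, -1.13 for Atoh8, -1.08 for Trp53cor1, -0.88 for Pik3ip1 and -0.88 for Nim1k. Of 35 splits of the 8 mice 1, the real one, gave as many calls (773, with 0 in the others). A share of 1 in 35 is the smallest this test can give. The other splits mix CNO and vehicle mice, which widens their spread, so the test does not exclude chance.

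Lower depth of the input libraries is argued against as the cause of the larger effect in IP: with the IP reads thinned to 36.9 M per library, the mean of the input libraries, a median of 0.924 of the 773 interaction genes passed again (0.915 to 0.940 over 10 draws, 707 to 727 genes). Dilution of astrocyte RNA by RNA of other cells in the input stays open. From the ratio of input to IP CPM of the astrocyte markers (0.160), the rise in input was predicted for the genes higher in CNO IP. The median ratio of observed to predicted rise was 0.672 (quartiles over genes -0.0232 to 1.30). This median lies just within the range set for dilution beforehand, 0.67 to 1.5. Its bootstrap interval over genes, 0.631 to 0.715, crosses the lower limit of that range, which is the stricter reading made afterwards. The interval leaves out the spread between libraries and that of the marker ratio (quartiles 0.138 to 0.195). The 283 genes with at least a 2-fold rise and 5 CPM gained in IP had a median of 0.756 (quartiles 0.562 to 1.01). Dilution alone and an effect that is also smaller in the input cannot be told apart here, because the interval crosses that limit, and a CNO effect on ribosome loading in astrocytes was not tested.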

How the results depend on the processing

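The pseudocount of 1 in the gene tests and the prior count of 2 in the list tests were alternatives chosen after seeing the data. The quasi-likelihood and Wald tests of counts named in the design were not run, since the deposited unit is log2. The minimum 2-fold change was applied to the counts of genes and not to single genes. Over the named genes and the list members given as examples, most of which had passed, and the other alternatives, 8850 values kept direction and side of the threshold, 351 kept direction and were no longer past it, 0 passed newly and 34 reversed, all of these in genes that had not passed. Of the list members given as examples, 83 of 103 kept their call in IP under every other alternative, 28 of 41 in input, 215 of 231 for IP against input in vehicle and 39 of 46 for the interaction. No median of a called list changed sign under either scaling. Limma-voom called 2649 of the 2700 genes in IP, 153 of the 158 in input, 11812 of 11902 and 11830 of 11861 for IP against input in vehicle and CNO, and 746 of 773 for the interaction. In simulated reads, 1.5-fold changes were recovered in 78.8 to 91.0% of cases and 2-fold changes in 83.6 to 100%. All genes of a simulation had the same dispersion, so genes of wider spread are not covered.

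Requiring a 2-fold change left 380 higher and 49 lower genes in IP, 59 and 0 in input, 2443 and 2308 for IP against input in vehicle, 2592 and 2090 in CNO, and 170 and 4 for the interaction, by construction. Upper quartile scaling gave 1946 lower genes in IP and 198 genes on the lower side of the interaction. There, median-of-ratios size factors gave 155 and a pseudocount of 5 gave 154. With these scalings the counts moved with the centre of the values, and for the pseudocount the cause was not tested. In the fit of all 16 libraries, input had 196 higher and 105 lower genes, with a spread shared over 4 groups. The mouse as a replicate block gave 1018 and 222 in the interaction and moved no other count of the fits paired by mouse by over 1.5 times; of their list calls it ended that of the excitatory postsynaptic genes (adjusted p = 0.0736) and no other.

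The replicate numbers of CNO and vehicle mice do not pair the injections: same-numbered libraries had correlations of -0.368 to 0.138 in IP and -0.596 to 0.028 in input, and 0 of 8 correlated best with their own number. With that number as a replicate block, IP had 1237 higher and 717 lower genes and input 95 and 7; the block uses up degrees of freedom.

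Camera with an estimated correlation called 3 lists higher and 0 lower in IP, and 0 and 0 both in input and for IP against input in vehicle. Fry called 14 higher and 0 lower in IP, 8 and 1 in input, and 20 and 11 for IP against input in vehicle; fry tests whether the genes of a list move one way, not whether they move more than other genes.

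Leaving out 1 library gave 1185 to 1745 higher and 596 to 1213 lower genes in IP, 85 to 155 and 4 to 27 in input, 5589 to 5898 and 5386 to 5775 for IP against input in vehicle, and 5995 to 6355 and 5044 to 5426 in CNO. Leaving out 1 mouse gave 471 to 625 and 35 to 69 for the interaction. Lists called higher and lower numbered 12 to 13 and 0 to 5 in IP, 11 to 14 and 3 to 8 in input, and 12 to 14 and 5 to 7 for IP against input in vehicle. Some of these fits gave more calls than the full one, and the cause was not tested.

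Log2 changes near 0 reversed for genes that had not passed. In IP, upper quartile scaling gave -0.000977 for Rpl22 and -0.0315 for Slc1a3. In input, median-of-ratios size factors gave 0.0150 for Slc1a3. In the interaction, median-of-ratios size factors gave -0.00483 for Rpl22, -0.00562 for Slc1a3 and -0.0167 for Aqp4, and upper quartile scaling gave -0.0200 for Rpl22, -0.0208 for Slc1a3 and -0.0318 for Aqp4. Leaving out 1 library gave ranges in IP of -0.0422 to 0.0824 for Slc1a3, -0.0792 to 0.0270 for Aldh1l1, -0.0611 to 0.132 for Rpl22 and -0.182 to 0.00768 for Slc1a2. In input they were -0.0867 to 0.167 for Slc1a2, -0.0667 to 0.374 for Kcnj10, -0.0436 to 0.115 for Rpl22, -0.0788 to 0.132 for Chrm4 and -0.0640 to 0.0309 for Slc1a3. In the interaction they were -0.0359 to 0.115 for Rpl22, -0.239 to 0.0448 for Slc1a2 and -0.0183 to 0.0785 for Aqp4. Insc lost its input call with the replicate block (adjusted p = 0.0995) and in the fit of all 16 libraries (0.327), and Lmcd1 with the block (0.0688). S100b lost its IP call with median-of-ratios size factors (0.0521), the block (0.0545) and the fit of all 16 libraries (0.115), Gja1 in that fit (0.0646), and Saa3 its ratio of IP to input with limma-voom (0.116); the cause was not tested. In IP the largest adjusted p over the alternatives was 0.215 for Camk2d, 0.238 for Fgf1 and 0.0576 for Dnaja1, which kept their calls without any 1 library.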

Other observations

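The tests of neuronal RNA in general, of length and GC content in the second interneuron list and of carried-over input RNA were chosen after the result was seen. Members of further lists fixed beforehand passed in CNO IP. Growth factors and cytokines rose for 7 of 24 members, Cxcl1 (log2 5.09), Clcf1 (3.78), Ccl2 (2.49), Lif (2.21), Fgf2 (1.85), Hbegf (1.81) and Il6, and Fgf1 fell by 0.17 (7 and 1 adjusted over the list alone). The call of Fgf1 held without any 1 library but was lost under another alternative. The growth factor and cytokine list had adjusted p = 0.0520, with a median of -0.01, and a mean of 0.99 and a test that pointed up. In input Il6, Lif (1.88), Fgf2 (1.57), Cxcl1 (2.46) and Hbegf (0.57) rose among 27 (7 adjusted over the list alone; adjusted p = 0.00150, and adjusted p = 0.236 with an estimated correlation). Of these, Cxcl1 (up to 0.130 without each CNO library or vehicle input replicate 4) and Hbegf (up to 0.136 without CNO input replicates 3 or 5 or vehicle input replicates 2, 3 or 4) lost their calls. Of 20 glucocorticoid-responsive genes 8 rose in IP (9 higher and 1 lower adjusted over the list alone), with Map3k6 at 2.61, the metallothioneins Mt2 at 1.37 and Mt1 at 0.70, and the clock gene Per1 at 0.90 (adjusted p = 0.00622, and adjusted p = 0.639 with an estimated correlation). In input Mt2 (1.28), Map3k6 (1.21) and Mt1 (0.49) rose (7 adjusted over the list alone; adjusted p = 1.15e-09, and adjusted p = 0.197 with an estimated correlation). Mt1 had up to adjusted p = 0.135 without each library but CNO input replicate 2. Of 13 heat shock genes 7 rose in IP (7 adjusted over the list alone), with Bag3 at 3.03, Hspb1 at 1.24, Hspa1a at 0.86 and Dnaja1 at 0.19, and Bag3 rose in input (2.00; 1 alone). Dnaja1 kept its call in IP without any 1 library but lost it under another alternative. The heat shock list had adjusted p = 3.10e-04 in IP and 1.02e-04 in input, and adjusted p = 0.470 and adjusted p = 0.411 with an estimated correlation. Rsad2 rose by 1.07 among 22 interferon-stimulated genes in IP (1 adjusted over the list alone; adjusted p = 0.0296, and adjusted p = 0.903 with an estimated correlation). The call was lost without CNO IP replicates 3 (0.0921) or 4 (0.0608) or vehicle IP replicates 3 (0.509) or 4 (0.0523). In input the interferon-stimulated genes were called higher (adjusted p = 0.0235) with 0 members past limma, limma-voom or an unadjusted p under 0.05, and had adjusted p = 0.846 with an estimated correlation. The call was lost without CNO input replicates 3 (0.0752) or 4 (0.146) or vehicle input replicates 3 (0.959, with the direction turned to lower) or 4 (0.10), and with median-of-ratios size factors (0.0889).

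Of 17 circadian clock genes Nfil3 (2.12), Bhlhe40 (1.23) and Per1 rose in CNO IP, and Dbp (-1.08), Nr1d1 (-0.47), Per3 (-0.35), Tef (-0.30) and Nr1d2 (-0.24) fell (4 and 8 adjusted over the list alone; adjusted p = 0.449, the test and median of -0.14 pointing down and the mean of 0.06 up). Of 24 glycolysis and glycogen genes the hexokinase Hk2 (1.71), Ppp1r3c (1.62), the glucose transporter Slc2a1 (1.27) and Pfkfb3 (1.25) rose (4 adjusted over the list alone; adjusted p = 0.0565; median 0.04, and -0.02 with upper quartile scaling). Of 20 extracellular matrix genes the protease Adamts1 (3.06), Fn1 (1.02), Tnc (0.60) and Mmp14 (0.52) rose and Hapln1 (-0.52) and Itga6 (-0.33) fell (5 and 2 adjusted over the list alone; adjusted p = 0.733). Of 20 calcium handling genes Rcan1 (1.64), Camk2d (0.42) and Calr (0.25) rose and Slc8b1 (-1.08) and Orai3 (-0.55) fell (3 and 2 adjusted over the list alone; adjusted p = 0.733). Of 25 Gi/o signalling components and adenylyl cyclases Rgs2 rose by 1.46 and Gnai2 fell by 0.22 (1 and 0 adjusted over the list alone; adjusted p = 0.733, the test and median of -0.05 pointing down and the mean of 0.03 up). Of 17 synaptogenic and synapse-modulating factors Thbs1 alone passed, also under both other scalings (1 adjusted over the list alone; adjusted p = 0.733). Of 16 phagocytic genes Pros1 (0.62), Megf10 (0.23) and Itgav (0.23) rose and Itgb5 (-0.45), Gas6 (-0.32) and Gulp1 (-0.27) fell (3 and 3 adjusted over the list alone; adjusted p = 0.733). Of 13 potassium, water and gap junction genes Hepacam (-0.36), Kcnj16 (-0.29) and Gja1 fell (3 adjusted over the list alone; adjusted p = 0.166). Slc7a11 rose (0.78) among 14 glutamate and GABA genes (1 alone; adjusted p = 0.355), and Atp5d rose (0.31) and Ndufa2 fell (-0.25) among 33 nuclear-encoded oxidative phosphorylation genes (1 and 1 alone; adjusted p = 0.0607).

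Camk2d kept its call without any 1 library but lost it under another alternative. Some of the other calls in these lists were lost without 1 library. They were Tnc (vehicle IP replicate 4, adjusted p = 0.0542), Calr (vehicle IP replicate 4, 0.0564), Gulp1 (vehicle IP replicate 2, 0.0590), Kcnj16 (CNO IP replicate 4 or vehicle IP replicate 4, up to 0.0558), Itga6 (each but CNO replicate 4 and vehicle replicate 2, up to 0.0810), Gnai2 (each but vehicle replicate 3, up to 0.126), Megf10 (each but CNO replicates 3 and 5, up to 0.0625), Pros1 (each but vehicle replicates 3 and 5, up to 0.0842), Itgav (each but CNO replicate 2 and vehicle replicate 5, up to 0.102), Gas6 (CNO replicates 2, 4 or 5 or vehicle replicates 2 or 4, up to 0.0936) and Gja1 (each but CNO replicate 3 and vehicle replicate 5, up to 0.0776). In vehicle mice, IP was higher than input for 13 of 13 potassium, water and gap junction genes, 12 of 14 glutamate and GABA genes, 16 of 20 extracellular matrix genes, 18 of 24 glycolysis and glycogen genes, 14 of 20 glucocorticoid-responsive genes, 17 of 22 interferon-stimulated genes, 11 of 16 phagocytic genes, 11 of 17 synaptogenic factors and 10 of 13 pan-reactive genes, lists that were all called higher. Over all genes tested in this comparison, 5978 of 15903 were higher. Adjusted over the list alone the list counts were equal, except for 12 phagocytic genes, and the complement genes C1qa, C1qb and C1qc were lower. Lower members of the other lists were Slc6a6 (-0.50) of the glutamate and GABA genes, Nid1 (-0.88) and Col4a1 (-0.23) of the matrix genes, and Hk2 (-1.06), Slc16a3 (-0.80) and Gapdh (-0.63) of the glycolysis genes. Fkbp5 (-0.63) and Klf9 (-0.20) were lower among the glucocorticoid-responsive genes, and Tgfb1 (-1.69), Nlgn1 (-0.97) and Nlgn2 (-0.23) among the synaptogenic factors. Col4a1 lost its call without vehicle input replicates 2, 4 or 5 or vehicle IP replicates 4 or 5 (adjusted p up to 0.0690), and Hk2 without vehicle IP replicate 3 (0.0533). None of the lists held with an estimated correlation (adjusted p = 0.172, 0.308, 0.172, 0.172, 0.25, 0.826, 0.478, 0.220 and 0.822), and pan-reactive genes lost the call without vehicle IP replicate 5 (0.0587). The blood marker Alas2 had a log2 ratio of -3.95.

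Transcripts of interneurons were higher in IP than in input while those of medium spiny neurons were lower. A second list of 12 other interneuron genes, written down before its values were seen, had a median log2 ratio of 1.77 in vehicle mice (quartiles 1.56 to 2.35; 10 of 12 passed, Gbx1 and Cort did not), with Tacr1 at 2.77, Slc17a8 at 2.62 and Ecel1 at 2.33. As the cause of the higher interneuron ratios, neuronal RNA in general carried into the IP is argued against by the medium spiny neuron median of -1.55. That median shows depletion relative to input, not absence of neuronal RNA from the IP. Length and GC content were those of the longest transcript of each gene, which need not be the one measured. With that limit they are argued against by the second list's median lying 1.93 above matched genes (1.42 to 2.30). In the first list the difference of 2.05 had an interval of 0.928 to 2.46, which left length and GC content open. Both intervals come from resampling the genes of a list and leave out the spread between libraries. A candidate explanation is that some interneurons carried the ribosome tag, in a share that these relative levels leave open.

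Cytosolic ribosomal protein transcripts were higher in CNO IP by a median of 0.21, with 20 of 79 members past the threshold. The list lay 0.278 above genes matched on length, GC content and level (0.244 to 0.306). Length and GC content stay open all the same, because they were those of the longest transcript of each gene, which need not be the one measured. Input RNA carried over into CNO IP is argued against: 905 other genes as depleted from IP as the middle of this list had a median CNO effect of 0.0292 (0.0138 to 0.0428). Both intervals come from resampling genes and leave out the spread between libraries. How closely the matched genes resembled the list was not checked. Reads shared with the many pseudogenes of ribosomal protein genes were not tested and stay open. An effect of CNO on these transcripts in astrocytes may also underlie the rise, as a hypothesis from the same libraries, and the list's call was lost with an estimated correlation (adjusted p = 0.359).

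Of 35 splits of the 8 libraries of CNO and vehicle, in IP and in input, 1, the real one, gave as many calls. The real count was 2700 for CNO against vehicle in IP (at most 0 in the other splits). In input it was 158 (at most 3). A share of 1 in 35 is the smallest this test can give. The other splits mix CNO and vehicle libraries, so a strong difference itself widens their spread and lowers their counts. The test therefore does not exclude chance. IP and input are paired by mouse, and the 8 splits that part every pair are too few for a share under 0.05; the restriction to them was set after the counts were seen. The real counts there were 11902 in vehicle and 11861 in CNO, against at most 0 in the other splits, which swap the RNA types of some mice.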
